A study of Homo sapiens with 10 samples.

How the data were processed

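γH2A.X ChIP-seq peak lists of 7 libraries were analysed: control H9 cells undifferentiated, on day 3 of neural and on day 3 of hematopoietic differentiation, S139E cells undifferentiated and on day 3 of neural differentiation, and S136/139A cells undifferentiated and on day 3 of hematopoietic differentiation. Per the labels, cells were fixed with 1% formaldehyde, chromatin was sonicated to 250 to 500 bp and precipitated with an antibody against phospho-S139 H2A.X, and each library was sequenced paired-end in 2 runs to about 31500000 clusters. The 3 input libraries carried no list and were not analysed here. FastQC, Bowtie2, Picard and HOMER are named by the submitters' processing notes, without versions or roles, with the build hg38. Per the file headers, the peaks were annotated with HOMER's annotatePeaks.pl against hg38. The settings of peak calling, the use of the input and the filters are not given in the sources used here. Each list belongs to 1 library, and no pooling of libraries is recorded.

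The peak score is the authors' own value, as deposited. In each list the distinct scores below 10 (19 to 32 values, carried by 88.4% to 97.4% of the peaks) were within 0.0051 of whole multiples of a step, which differed between lists, as a tag count scaled to a fixed total gives. Higher scores were not checked. If that total is 10000000, HOMER's usual scale, the steps give about 43000000 to 65400000 tags per library; the scale is not stated, but the ratio of depths between libraries does not depend on it. Scores were used to rank peaks within a list, for the share of the summed score held by wide peaks, and, through the step, for tags per library and per peak; they were not compared between lists. Positions, widths, distances to the transcription start site and the annotation class (promoter, exon, intron, UTR, intergenic) are other values taken as deposited by the authors. A peak belongs to the gene with the nearest start site, which may be far away. The annotated intron or exon can lie in a different gene from the assigned one. Some gene symbols in the lists had been turned into dates (28 peaks in all) and were restored through the Entrez gene number. A table of RefSeq genes of GRCh38.p14 gave current symbols, gene spans and lengths; 99.3% to 99.5% of peaks had a gene number in it.

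Peaks outside chromosomes 1 to 22 and X were left out of all comparisons (6 to 60 per list). Mappability and lists of hg38 regions to exclude were not available, so no peak was left out for its mapping. The share of peaks in promoters follows the annotation class, with an exact Clopper-Pearson 95% interval. The table of genes did not allow the same class for random positions, so the share of peak centres in gene spans was set beside that of random positions instead. For each of 8 pairs of libraries, the share of the shorter list that overlapped the longer list by at least 1 bp was computed with its exact interval and set beside 1000 random placements of the shorter list (same widths, same chromosome). Placements moved by 50 to 500 kb were added after the data were seen, because peaks gather in the same broad regions in several lists. For a count of 0, the share that 3 counts would give is the limit. Intervals and limits cover counting error only.

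For gene lists, the number of members with at least 1 assigned peak was set beside 10000 random lists of protein-coding genes (19974 genes in 20 bins of gene length); ties count at their middle. The percentile describes the library and is not a test between conditions, since genes are not replicates. Shared genes were compared with the number expected for independent lists within the same length bins. The lists were pluripotency, neural ectoderm, mesoderm and hematopoietic, endoderm, trophectoderm and amnion, neural crest, HOX clusters, DNA damage response, cell cycle, common fragile site genes, synaptic and neural adhesion genes, signalling (WNT, TGF-β, FGF and Notch), chromatin regulators, and, by symbol, olfactory receptors, zinc finger genes, protocadherins, histone genes and keratins. The histone pattern takes the replication-dependent genes and also linker histone genes whose symbol begins with H1. Some lists share members. Lists of heat-shock proteins, immediate early genes, splicing factors and ribosomal proteins were made after the strongest peaks had been seen.

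Groups, comparisons, gene lists and the rule for named genes were fixed before the data were examined. The rule takes, for each pair of libraries, the genes of the 8 highest-scoring peaks of each list without an overlap in the other and up to 8 lineage genes with a peak in only 1 of them; for each library, the genes of its 5 highest-scoring peaks and the 3 genes with the most peaks; for each gene list, up to 4 members with the highest-scoring peaks; and H2AX. Genes known only by a LOC number were passed over as unnamed. The ABCA4 and GCLM positions shared by several lists, the wide peaks, and the distribution over repeats and chromosomes were chosen after their values were seen. With 1 library per group no test between conditions was planned. An additive model was added after the data were seen: least squares on the log2 values of the 7 libraries, with terms for the neural day, the hematopoietic day, S139E and S136/139A. For gene lists the value was the log2 ratio of observed to random mean genes, each plus 0.5. The model takes the effect of a day to be the same in all cell types, and its 2 residual degrees of freedom measure how far the cell types differ in that effect, not the spread between replicates. State labels were permuted within each cell type and cell type labels within each state (24 arrangements each), with the ratio of explained to residual variation of the term as the statistic.

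The overlap step was tested on simulated data: of control undifferentiated peaks placed so that 4.99% and 30.0% overlapped the control neural list (3469 peaks), 5.16% and 30.2% were counted. The gene-list step was tested on lists of long genes with no enrichment, of which 2.50% passed percentile 97.5 with length matching and 100% without. In that test each gene received peaks independently, by its length alone, so it does not cover families of neighbouring genes. Alternatives were a stricter overlap (at least 50% of both peaks), a looser one (within 1 kb), the upper 50% of each list by score, lists of the same length, joining peaks within 10 kb, promoter windows of 1 kb and 5 kb, gene assignment within 100 kb or from promoter peaks only, and random lists without length matching. Leaving out peaks of 1 kb or wider and matching random lists on the distance between neighbouring genes were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.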

Results

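The series mapped H2A.X phosphorylated at the serine S139 (γH2A.X), a histone mark best known from chromatin around DNA double-strand breaks, in H9 cells, an established human embryonic stem cell line. Chromatin was cross-linked, sonicated and immunoprecipitated with an antibody to the phosphorylated residue, and the recovered DNA was sequenced (ChIP-seq). There were 3 cell types. Control cells carried an empty vector. S139E cells carried H2A.X with this serine replaced by glutamate, an exchange often used to imitate a phosphate. S136/139A cells carried H2A.X with this and a neighbouring serine replaced by alanine, which cannot be phosphorylated. Cells were taken undifferentiated (day 0) or on day 3 of neural or hematopoietic differentiation. Of the 10 libraries, 7 were immunoprecipitates with a peak list and entered the comparisons; the 3 input libraries were not analysed here. Every group held 1 library, so each comparison below is between 2 libraries, no replicate error exists, and the exact intervals cover counting error only. An additive model of state and cell type over the 7 libraries, chosen after the data were seen, leaves 2 residual degrees of freedom. Exact permutation tests of its terms for state and cell type, with Benjamini-Hochberg adjustment, passed 0.05 in 0 of 8 tests on the number of peaks and the promoter, LTR and satellite shares (lowest adjusted p = 0.167). They passed in 0 of 36 tests on the gene lists fixed in advance (lowest adjusted exact permutation p = 0.375). With 24 arrangements no unadjusted p can be below 0.0417. After adjustment a pass would have needed nearly all tests of a family at that lowest value. The counts of 0 therefore do not show that effects of state or cell type are absent. The antibody recognises the phosphorylated form of the residue that both mutations replace. Since alanine cannot be phosphorylated, any specific signal in S136/139A cells would come from endogenous H2A.X. Whether the antibody binds the glutamate of S139E is not known here, so in those cells the lists do not tell endogenous from mutated H2A.X.

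The number of peaks differed 19.8-fold between the longest and the shortest list. On chromosomes 1 to 22 and X, the control cells had 3469 peaks undifferentiated, 6858 on the neural day and 1640 on the hematopoietic day. The S139E cells had 4276 peaks undifferentiated and 8555 on the neural day. The S136/139A cells had 433 peaks undifferentiated and 980 on the hematopoietic day. The neural day thus had 1.98 times as many peaks as the undifferentiated state in control cells and 2.00 times as many in S139E cells. The hematopoietic day had 0.473 times as many in control cells and 2.26 times as many in S136/139A cells. S139E lists were 1.23 times (undifferentiated) and 1.25 times (neural day) as long as the control lists, and S136/139A lists 0.125 times (undifferentiated) and 0.598 times (hematopoietic day) as long. The order of the lists did not follow depth. If the score is a tag count scaled to 10000000, the score steps put the libraries at about 43000000 to 65400000 tags, and the S136/139A hematopoietic library had the most. The median peak held 31 to 39 tags and the weakest listed peak 24 to 33, so most peaks lay close to the calling limit.

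Most peaks lay in introns or between genes, and promoters held a small share that was largest on the hematopoietic day. In control cells, 3.34% of peaks (95% interval 2.77 to 4.00) were annotated to promoters in the undifferentiated state, 4.56% (4.08 to 5.08) on the neural day and 8.23% (6.95 to 9.67) on the hematopoietic day. In S139E cells the share was 2.95% (2.46 to 3.50) undifferentiated and 5.30% (4.83 to 5.79) on the neural day. In S136/139A cells it was 0.924% (0.252 to 2.35, from 4 of 433 peaks) undifferentiated and 10.9% (9.03 to 13.0) on the hematopoietic day. The intervals of the day 3 and undifferentiated libraries did not overlap in any of the 3 cell types. Introns held 44.7% to 56.8% of peaks, the most in the control hematopoietic library, where 79.8% of peaks (77.7 to 81.7) were centred in a gene span against 56.2% of random positions. In the other 6 libraries that share was 59.8% to 71.3%. No library had a peak assigned to H2AX, the gene of the histone itself. A wider promoter window of 5 kb around the start site raised the shares to 8.55% to 39.5%, with the 2 hematopoietic libraries still highest.

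**Figure D1:**
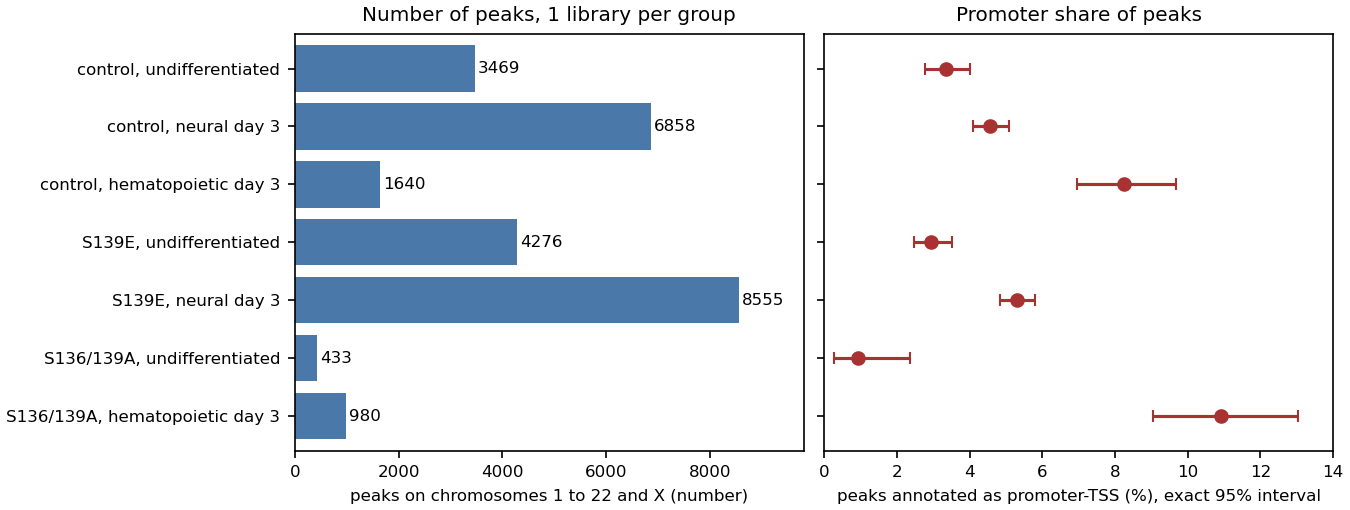
Number of peaks on chromosomes 1 to 22 and X (left, bars, 1 library per group) and percent of those peaks annotated to promoters (right, points with exact 95% intervals) in the 7 libraries. The S139E neural list was the longest with 8555 peaks and the S136/139A undifferentiated list the shortest with 433, while the promoter share was highest, at 10.9%, in the S136/139A hematopoietic library.

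The lists had few positions in common. Of the 26211 peaks on these chromosomes, 93.0% overlapped no peak of another list, 6.70% overlapped a peak of 1 other list, and 0 overlapped peaks of all 7 lists. The position found in the most lists, 5, lay in ABCA4, which encodes a retinal lipid transporter: the control undifferentiated peak there covered chromosome 1, 94078205 to 94079033 (hg38), was centred in an exon and had a score of 23.1. The S136/139A hematopoietic peak at this position was annotated to a simple repeat in an intron. A second position in the same gene, centred in an intron and assigned to GCLM as the nearest start site (chromosome 1, 94008618 to 94009244), was found in 4 lists and had the highest score of the control undifferentiated list, 32.5.

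**Figure D2:**
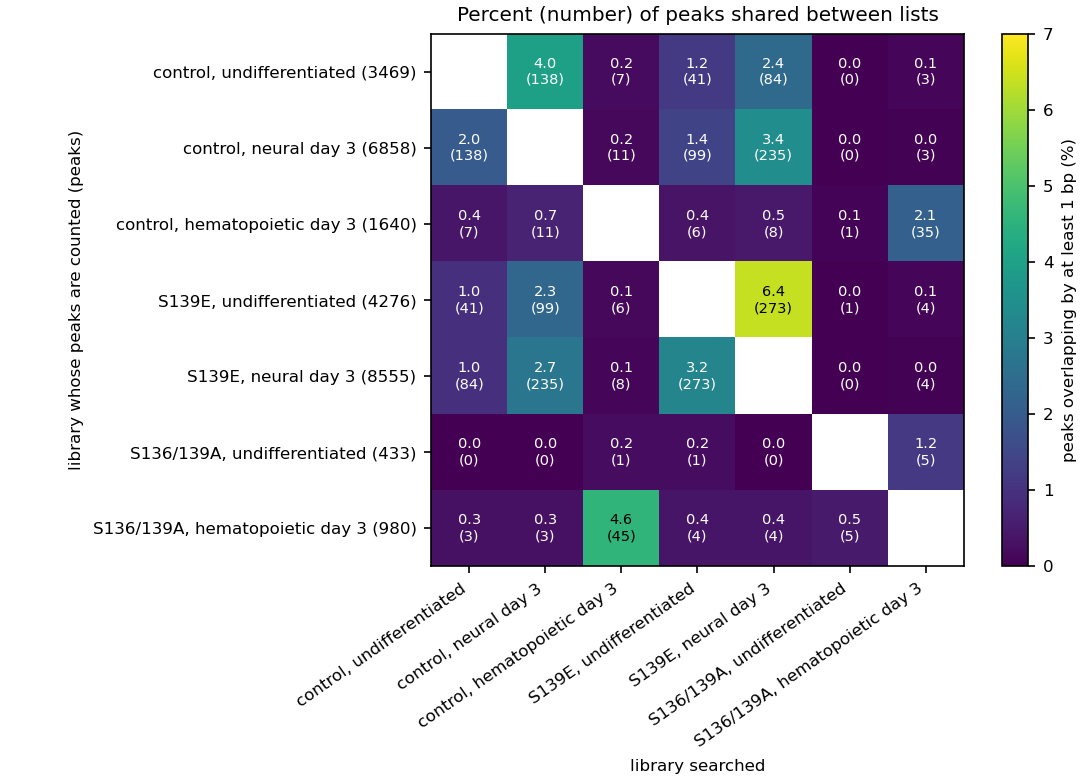
Percent and, in brackets, number of the peaks of each library (row) that overlap a peak of another library (column) by at least 1 bp; the colour gives the percent. The largest shares were 6.4% (273 peaks of the S139E undifferentiated list in the S139E neural list) and 4.6% (45 peaks of the S136/139A hematopoietic list in the control hematopoietic list).

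What changed with neural differentiation was asked first in control cells. The strongest peaks of the neural library without a counterpart in the undifferentiated library included an intergenic one assigned to CHEK2P2 from 73.9 kb away (chromosome 15, 20356299 to 20356938, score 22.3). Another lay in an intron on chromosome 19 (45145965 to 45147167, score 19.7). It was assigned to NKPD1, the nearest start site, from 13.6 kb away. Others lay at the promoter of CFAP119 (score 18.1) and in the 5′ UTR of MARCHF4 (chromosome 2, 216371182 to 216372412, score 17.7), which encodes a ubiquitin ligase. The pluripotency genes ZFP42, with a peak in an exon (score 9.06), and UTF1, with a peak assigned from 10.4 kb upstream (score 7.96), had a peak on the neural day and none in the undifferentiated state. The reverse held for FGF4 (score 8.07), for the mesendoderm gene GSC, with a peak in an exon (score 7.85), and for MAP2 (8.75), IRX3 (7.85), GFI1B (8.07) and HHEX (7.63), all but GFI1B of these last 4 with intergenic peaks. Of the neural ectoderm list, 6 of 37 genes had a peak in each library. The libraries shared 138 of 3469 peaks, 3.98% (3.35 to 4.68), which was 14.4 times the 0.277% of random placements and 7.48 times the 0.532% of placements within 500 kb of the true position. They shared 883 protein-coding genes with an assigned peak, where 440.6 were expected for lists drawn independently at matched gene length. In all, 3719 such genes had a peak on the neural day and 2161 in the undifferentiated state. A peak in only 1 of the 2 lists was thus the common case for any gene. With both lists cut to the same length the shared share was 2.39%.

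In S139E cells the neural ectoderm list had peaks in 14 of 37 genes on the neural day (7.68 in random lists, percentile 99.2) and in 10 in the undifferentiated state (4.15, percentile 99.6). The neural value was 88.1 in the upper 50% of peaks and 97.48 within 100 kb. On the neural day a peak covered the 5′ UTR of PAX6, a transcription factor of the neural plate and eye (chromosome 11, 31810369 to 31811298, score 10.9), and others lay in the single exon of SOX3 (chromosome X, 140504614 to 140505275, score 7.88), in an exon of NES, which encodes the intermediate filament nestin (7.88), and distal to EN2 (7.88). None of these 4 genes had a peak in the undifferentiated S139E library. LEFTY2, an inhibitor of Nodal signalling (score 8.37), IRX3 (8.14), CDH5 (7.91) and GATA2 (7.91) had peaks only in the undifferentiated one of these 2 lists. The strongest unshared peaks of the neural day included those in an exon of PARP10, an ADP-ribosyltransferase (chromosome 8, 143983368 to 143985406, score 25.0), and in introns of KCNT1 (22.8) and ABR (20.6), and those of the undifferentiated state included introns of JPH3 (17), ADAMTS2 (15.8) and LETM1 (15.6). The libraries shared 273 of 4276 peaks, 6.38% (5.67 to 7.16), 16.8 times the random value of 0.381% and 6.94 times that of local placements. With lists of the same length the share was 4.02%. They shared 1199 genes against 576.1 expected, of 4330 with a peak on the neural day and 2533 in the undifferentiated state.

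Hematopoietic differentiation of control cells gave a list led by wide, strong peaks over genes of the heat-shock response. The strongest covered HSP90AA1, a cytosolic chaperone (chromosome 14, 102076142 to 102087271, score 479.3), followed by DNAJB1, a co-chaperone (chromosome 19, 14512297 to 14518718, score 300.2), HSPH1 with 2 peaks (the stronger on chromosome 13, 31147692 to 31161429, score 256.6), the MALAT1 locus, assigned to MASCRNA (230.0), SERPINH1, a collagen chaperone (190.4), ACTB (163.1) and HSPA5, the chaperone of the endoplasmic reticulum (152.7). None of these peaks overlapped a peak of the control undifferentiated library. The list held 34 peaks of 2 kb or wider, up to 14493 bp, against 0 to 2 in each of the other 6 lists, and these 34 held 22.8% of the summed score of the list. Among lineage genes, BMP4 (intergenic, 114 kb upstream, score 14.2) and CDH2 (intergenic, 10.4) had a peak on the hematopoietic day and not in the undifferentiated state. CDH5 (8.97), FGF4 (8.07), GSC (7.85) and HHEX (7.63) showed the reverse, and 1 of the 38 mesoderm and hematopoietic genes had a peak (1.97 in random lists, percentile 26.6) against 8 in the longer undifferentiated list (4.28, percentile 96.3). The libraries shared 7 of 1640 peaks, 0.427% (0.172 to 0.877). Random placements gave 0.138% on average and up to 0.732%, so the excess was within the range of placements. The 138 shared genes, of 1016 with a peak on the hematopoietic day and 2161 in the undifferentiated state, were close to the 134.5 expected.

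**Figure D3:**
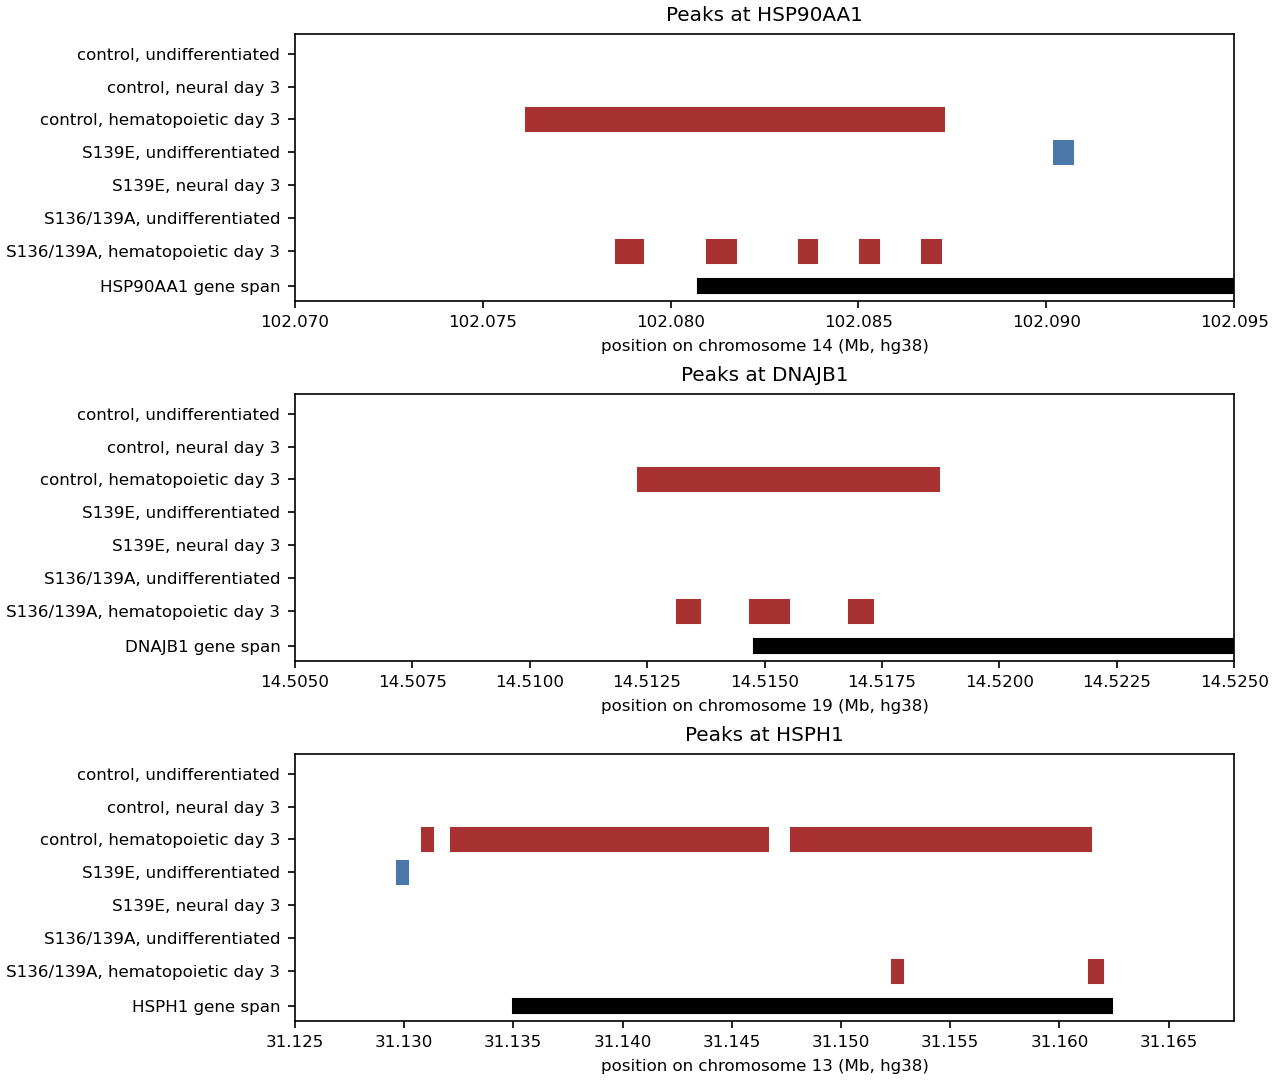
Peaks of the 7 libraries (rows; red, hematopoietic day, blue, other libraries) and the annotated gene span (black, cropped at the edge for HSP90AA1 and DNAJB1) at HSP90AA1, DNAJB1 and HSPH1, by position in Mb on hg38. The control hematopoietic library had peaks of 11129 bp at HSP90AA1 and 6421 bp at DNAJB1, and the S136/139A hematopoietic library had several narrow peaks in the same regions.

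In S136/139A cells 3 of the 38 mesoderm and hematopoietic genes had a peak on the hematopoietic day (1.27 in random lists, percentile 91.7) and 2 in the undifferentiated state (0.49, percentile 95), so the list did not stand out in either library. On the hematopoietic day a peak lay in an intron of BMP4, 0.818 kb from its start site (chromosome 14, 53952334 to 53952981, score 16.7); BMP4 is also one of the factors in the differentiation medium, per the labels. Others lay in the 3′ UTR of HAND1, a mesoderm and trophoblast transcription factor (chromosome 5, 154475282 to 154476146, score 11), in an intron of SALL4, a pluripotency factor (chromosome 20, 51797283 to 51798201, score 11.2), and 2.08 kb upstream of MEIS2 (9.33). None of these genes had a peak in the undifferentiated S136/139A library, where CD34, a marker of blood progenitors (6.44), and CSF3R (6.07) were assigned peaks over 100 kb away and had none on the hematopoietic day. The strongest peaks of the day without a counterpart there included the 2 positions in ABCA4 (40.8 and 31.8), the promoter of PGK1, a glycolytic enzyme (chromosome X, 78103827 to 78104452, score 31.0), the MALAT1 locus (24.8) and an intron of HSPA8 (17.6). With no input list, it was not checked whether these positions are also enriched in input DNA. The undifferentiated list was led by peaks in an intron of the non-coding gene FAM230C (chromosome 13, 18211866 to 18212366, score 47.6), near BAGE (29.6), and at positions assigned to ALG10 (23.9) and DCUN1D4 (17.8) from over 1 Mb away. Whether reads map uniquely at these positions was not checked. Satellite repeats held 6.0% of its peaks (3.96 to 8.67), against 1.53% (0.859 to 2.51) on the hematopoietic day. The libraries shared 5 of 433 peaks, 1.15% (0.376 to 2.67), against 0.0344% at random, and 23 genes against 13.8 expected. Of protein-coding genes, 646 had a peak on the hematopoietic day and 268 in the undifferentiated state.

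S139E cells were compared with control cells in both states. In the undifferentiated state, DLX2, a forebrain homeobox gene (8.37), LEFTY2 (8.37), LHX5 (7.91) and the blood and endothelial genes GATA2 (7.91) and PECAM1 (7.44) had a peak in S139E and none in control cells, and MAP2 (8.75) and HHEX (7.63) the reverse. The strongest unshared peaks included JPH3 (17), DKK4, an inhibitor of WNT signalling (16.3), and TP53I11 (15.8) in S139E cells, and GJA3 (16.8) and SLCO2B1 (16.6) in control cells. The libraries shared 41 of 3469 peaks, 1.18% (0.849 to 1.60), 6.64 times the random 0.178% and 3.46 times that of local placements. On the neural day, S139E cells had peaks at PAX6 (10.9), DLX2 (10.5), FGF4 (9.98), GSC (9.46), EMX1 (9.11), GFI1B (8.93) and TERT (8.23), none of which had a peak in control neural cells, while ZFP42 (9.06) showed the reverse. The libraries shared 235 of 6858 peaks, 3.43% (3.01 to 3.88), 9.06 times the random 0.378% and 3.69 times that of local placements. The shared genes numbered 611 against 299.5 expected in the undifferentiated state, of 2533 with a peak in S139E and 2161 in control cells. On the neural day they numbered 1624 against 844.4 expected, of 4330 and 3719. Most genes with a peak in 1 list thus had none in the other, and the named lineage genes do not stand out by this. The S139E neural library also had more tags than the control neural library, so depth may contribute to peaks found only in the former. Both shares of peaks moved by over 1.5 times with the rule: requiring that at least 50% of both peaks overlap gave 0.692% and 1.90%, and accepting peaks within 1 kb gave 2.42% and 6.39%.

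S136/139A cells were compared with control cells in both states. In the undifferentiated state the lists had no peak in common: 0 of 433, where counting error alone allows up to 0.693% and random placements gave 0.120%, so an overlap at the random level was not detectable at this length. Lineage genes with a peak in control cells and none in S136/139A cells included CDH5 (8.97), MAP2 (8.75), FGF4 (8.07) and GSC (7.85). Those of CDH5 and MAP2 were intergenic peaks 95 kb and 116 kb upstream. Of protein-coding genes, 2161 had a peak in control cells and 268 in S136/139A cells, and 54 had a peak in both, against 39.1 expected. Nearly all control genes thus lacked a peak in the shorter list, and the named lineage genes do not stand out by this. On the hematopoietic day the libraries shared 45 of 980 peaks, 4.59% (3.37 to 6.10), 73.2 times the random 0.0628%. They shared 124 genes against 45.7 expected, of 646 with a peak in S136/139A cells and 1016 in control cells. Of the 34 wide regions of the control library, including those at HSP90AA1, DNAJB1, HSPA5 and SERPINH1, 19 held a peak of the S136/139A library. Unshared peaks were at PGK1, BMP4, SALL4 and HAND1 in S136/139A cells and at PPP1R15A, a stress-induced phosphatase subunit (101.7), ACTG1 (82.5), BAG3, a co-chaperone (55.6), and HSPB1 (53.7) in control cells. Without peaks of 1 kb or wider, an alternative chosen after seeing the data, the shared share was 1.33%, and with at least 50% overlap of both peaks it was 0.918%.

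Among the gene lists fixed in advance, histone genes, neural ectoderm genes and signalling genes stood highest against 10000 random lists of the same size and gene lengths. Histone genes had a peak in 13 of 74 members in the control hematopoietic library (2.32 on average in random lists, percentile 100), among them H2BC5 (promoter, score 37.9), H3C12 (promoter, 12.3) and H4C5 (11.2), and in 5 of 74 in the S136/139A hematopoietic library (1.01, percentile 99.9), with H3C12 (5.96) again; the latter was 93.8 without length matching, and 0 genes remained in the upper 50% of that list (37.0). In the other 5 libraries 0 to 5 members had a peak and no percentile exceeded 38.2. Neural ectoderm genes with a peak numbered 14 of 37 on the S139E neural day (7.68, percentile 99.2), 10 in undifferentiated S139E cells (4.15, 99.6), 5 in the control hematopoietic library (1.65, 98.8) and 4 in the S136/139A hematopoietic library (0.93, 99.4), against 6 on the control neural day (6.33, 46.0). The upper 50% of peaks gave 84.9 in the control hematopoietic library, and peaks within 100 kb gave 88.7 in the S136/139A hematopoietic library. Random lists matched on the distance between neighbouring genes gave 96.8 in the control hematopoietic library. Genes of WNT, TGF-β, FGF and Notch signalling numbered 8 of 50 in the S136/139A hematopoietic library (1.83, 100.0), with BMP4 (16.7), SMAD7 (7.19), HES1 (6.88) and CTNNB1 (6.42), 7 in the control hematopoietic library (2.78, 98.6) and 11 in undifferentiated control cells (5.87, 98.0); within 100 kb the values of the 2 control libraries were 93.4 and 94.6, and in the upper 50% that of the hematopoietic one was 70.6. Mesoderm and hematopoietic genes numbered 11 of 38 in undifferentiated S139E cells (5.00, 99.5), neural crest genes 9 of 20 on the S139E neural day (4.30, 99.1) and 4 in the control hematopoietic library (1.05, 98.9), and trophectoderm and amnion genes 3 of 20 in the S136/139A hematopoietic library (0.53, 99.2). In the upper 50% of peaks the mesoderm value was 96.15 and the neural crest values were 83.2 and 94.1, and within 100 kb neural crest genes in the control hematopoietic library were at 96.0.

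The pluripotency list reached no percentile of 97.5 or more; its highest count was 10 of 32 genes on the S139E neural day (6.40, percentile 93.6), with FGF4 (9.98), TFCP2L1 (8.93) and TERT (8.23). DNA damage response genes had few peaks in S139E cells, 4 of 44 on the neural day (10.1 in random lists, percentile 0.92), of which CDKN1A, a cell-cycle inhibitor induced by p53, had the strongest (8.41), and 2 undifferentiated (6.21, 2.52); in the upper 50% of peaks the neural day was at 3.61. Olfactory receptor genes were at percentile 0.05 or lower in the control and S139E libraries, for example 22 of 392 on the S139E neural day (58.3). Zinc finger genes were below 2.5 in the 3 control libraries and on the S139E neural day (91 of 517, 114.0 in random lists, 0.78), but the control neural day (1.59) was at 3.67 in the upper 50% of peaks and at 4.69 with matching on the distance between genes. Protocadherins were below 2.5 in undifferentiated and neural control cells and on the S139E neural day, lowest on the control neural day (4 of 65, against 14 in random lists, percentile 0.04). With matching on the distance between genes all 3 protocadherin values were above 2.5, at 28.3, 3.04 and 28.2, so they depend on how the random lists are drawn; the first and the last were also above it in the upper 50% of peaks (20.1 and 27.4) and without length matching (11.3 and 5.68), and the first also within 100 kb (2.77). Endoderm genes, HOX clusters, cell cycle genes, common fragile site genes, synaptic and neural adhesion genes, chromatin regulators and keratins stayed between 2.5 and 97.5 in all 7 libraries; fragile site genes, which lie in very long genes, had a peak in 3 to 11 of 30 members. Of the 126 pairs of list and library, 13 were at or above 97.5 and 13 at or below 2.5. If genes received peaks independently of their neighbours, 3.15 of each would be expected by chance. Members of families that lie side by side can gain or miss peaks together, so that number is only a rough guide. Most of the 13 low pairs were of olfactory receptors, zinc finger genes and protocadherins. Counting promoter peaks only left 2 of the 13 high pairs, both of histone genes.

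**Figure D4:**
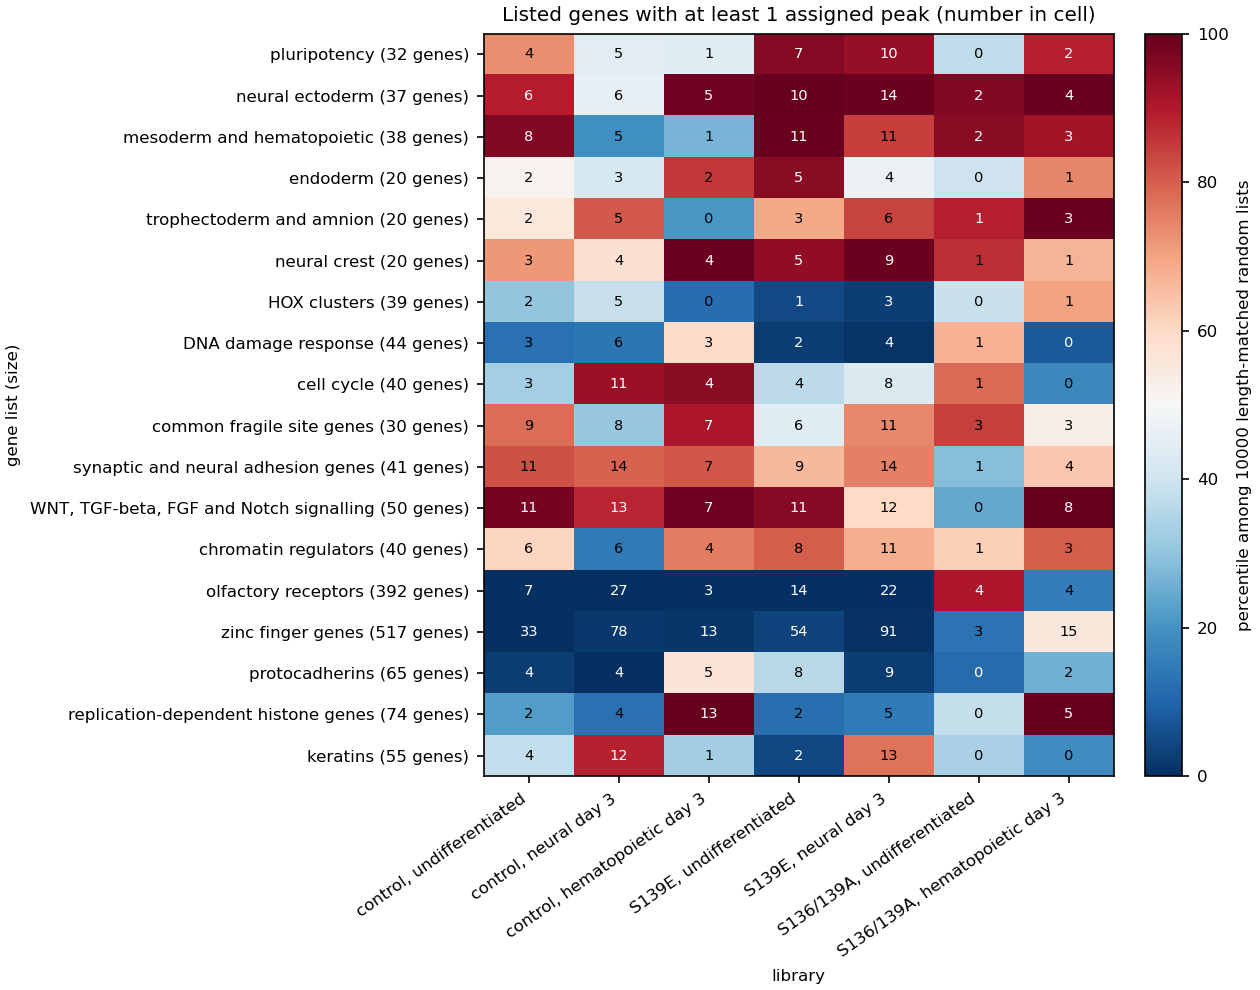
Percentile (colour) of the number of genes with at least 1 assigned peak (number in each cell) among 10000 random lists matched on gene length, for 18 gene lists (rows, with size) and 7 libraries (columns). Histone genes stood at percentile 100 in the control hematopoietic library, with 13 of 74 genes, and at 38.2 or lower in the 5 libraries that were not hematopoietic.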

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

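The tests in this part were chosen after the results were seen, except the promoter windows and the lists of the same length, which were planned. None of the differences below was tested, since each rests on 1 library per group that moved in the opposite direction from its counterpart, and the additive model takes such effects to be the same.

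The number of peaks on the hematopoietic day, relative to the undifferentiated state, was lower in control cells (log2 ratio -1.08) and higher in S136/139A cells (log2 ratio 1.18). Sequencing depth as the cause would need peaks and tags to move together; the tags were 1.17 times as many on the hematopoietic day in control cells and 1.20 times as many in S136/139A cells, so depth moved the same way in both, which argues against it. A difference in enrichment over background between the immunoprecipitates remains possible: with 0 input or replicate libraries that have a list, it cannot be told apart from an effect of the mutation or of the day. The weakest listed peaks held 24 to 33 tags, so a small change in enrichment could move many peaks across the calling limit.

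The promoter share of S139E against control cells was lower in the undifferentiated state (log2 ratio -0.18) and higher on the neural day (0.21); the intervals of the libraries overlapped in both states. The opposite direction depends on the annotation class: in the undifferentiated state S139E cells had 6.22% against 6.17% in control cells within 1 kb of a start site and 20.02% against 17.8% within 5 kb, and on the neural day 10.9% against 9.35% and 25.6% against 22.3%, so they were higher in both states. The promoter share of S136/139A against control cells was lower in the undifferentiated state (-1.86) and higher on the hematopoietic day (0.41), where the intervals of the libraries overlapped. Within 1 kb of a start site the opposite direction stayed, at 1.155% against 6.17% undifferentiated and 18.1% against 16.6% on the hematopoietic day. It also stayed with lists of the same length, at 0.924% against 4.85% and 16.2% against 10.2%. Within 5 kb of a start site S136/139A cells were lower in both states, at 8.55% against 17.8% and 32.0% against 39.5%. The share of peaks in LTR elements, remnants of retroviruses, was lower in undifferentiated S136/139A cells than in control cells (-0.82) and higher on the hematopoietic day (1.5). The share in satellite repeats on the neural day against the undifferentiated state was lower in control cells (-0.33) and higher in S139E cells (0.69). In satellites, S139E cells were lower than control cells undifferentiated (-0.52) and higher on the neural day (0.49); these shares rest on 18 to 58 peaks, and the intervals overlapped in each of these comparisons.

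Peaks outside chromosomes 1 to 22 and X entered no comparison. There were 14 in undifferentiated, 23 in neural and 7 in hematopoietic control cells, 39 in undifferentiated and 60 in neural S139E cells, and 21 in undifferentiated and 6 in hematopoietic S136/139A cells. They made up 4.63% of the undifferentiated S136/139A list and 0.334% to 0.904% of the other lists.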

How the results depend on the processing

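The alternative without peaks of 1 kb or wider and the matching on distance between genes were chosen after seeing the data; all others were planned. Pairing by replicate number was not used, since every group held 1 library. The additive model of state and cell type, also chosen after seeing the data, passed in 0 of 8 tests on library measures and 0 of 36 on gene lists (exact permutation, adjusted). Unadjusted, 2 and 4 were at 0.0417, the lowest value that 24 arrangements can give, among them the number of peaks by cell type and the promoter share by state. With so few arrangements the adjusted tests could hardly pass, so no conclusion is drawn from the counts of 0. Of 91 values of the main comparisons under an alternative, 42 stayed and 49 did not, where a share stayed if it lay within the interval of the main share and a number of peaks or list pairs if it was within 1.5 times of the main number. Of the percentiles of single gene lists, 109 stayed on their side of the limit, 33 did not reach it and 14 crossed to the other side of the middle. Leaving out regions found in all 7 lists removed no peak, since no such region exists, and shows nothing. The shares of the hematopoietic comparison in control cells (0.305% to 0.610%) and in S136/139A cells (1.15% to 2.31%) stayed within their intervals.

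Shares of shared peaks moved mostly by the construction of the alternative. With at least 50% of both peaks overlapping, they were 3.03% (neural day, control cells), 4.54% (neural day, S139E cells), 0.692% (S139E against control, undifferentiated), 1.90% (the same, neural day) and 0.918% (S136/139A against control, hematopoietic day). With peaks within 1 kb, the first 4 were 5.68%, 9.21%, 2.42% and 6.39%. In the upper 50% of each list by score, the 5 shares were 3.23%, 4.77%, 0.750%, 2.13% and 6.53%. With lists of the same length they were 2.39% (neural day, control cells), 4.02% (neural day, S139E cells) and 2.92% (S139E against control, neural day). Without peaks of 1 kb or wider, the share between S136/139A and control cells on the hematopoietic day was 1.33%, so the wide peaks carry most of that overlap.

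The upper 50% of each list holds by construction 1734, 3429 and 820 peaks in undifferentiated, neural and hematopoietic control cells, 2138 and 4277 in undifferentiated and neural S139E cells, and 216 and 490 in undifferentiated and hematopoietic S136/139A cells. In the same order of 7 libraries, the share of peaks within 5 kb of a start site was 17.8%, 22.3%, 39.5%, 20.02%, 25.6%, 8.55% and 32.0%, larger because the window is wider; within 1 kb it was 6.17%, 9.35%, 16.6%, 6.22% and 10.9% in the first 5 and 18.1% in hematopoietic S136/139A cells. In the upper 50% by score, the promoter share was 9.76% (hematopoietic control), 6.34% (neural S139E), 15.1% (hematopoietic S136/139A) and 0 of 216 (undifferentiated S136/139A, which allows up to 1.39%). With lists of the same length it was 4.85%, 6.24% and 10.2% in undifferentiated, neural and hematopoietic control cells, 7.62% in neural S139E cells and 16.2% in hematopoietic S136/139A cells; stronger peaks were thus more often at promoters in these 5 libraries, and the cause was not tested.

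Of the 13 low pairs in the main setting, 9 stayed with matching on distance between genes (protocadherins in 3 libraries and zinc finger genes on the control neural day were lost), 9 in the upper 50% of each list, 12 under the 100 kb limit, 11 without length matching, 13 without peaks of 1 kb or wider and 2 with promoter peaks only. The number of high pairs of gene list and library, 13 in the main setting, was 10 under the 100 kb limit (8 of them among the 13), 8 in the upper 50% of each list (6 among them), 18 without length matching (12 among them), 12 with matching on distance between genes (12 among them), 13 without peaks of 1 kb or wider (13 among them) and 2 with promoter peaks only. With promoter peaks, lists with 0 members having a peak fell below the middle by construction: neural ectoderm in hematopoietic control (percentile 42.3), undifferentiated S139E (43.4), neural S139E (25.0) and hematopoietic S136/139A cells (45.0), mesoderm and hematopoietic genes in undifferentiated S139E cells (42.9), trophectoderm genes in hematopoietic S136/139A cells (45.6), neural crest genes in hematopoietic control (46.0) and neural S139E cells (35.2), and signalling genes in undifferentiated (39.0) and hematopoietic control (37.6) and hematopoietic S136/139A cells (38.9). Zinc finger genes rose to 76.6 (4 genes, hematopoietic control) and 59.5 (10 genes, neural S139E). Histone genes in hematopoietic S136/139A cells, whose 5 peaks are weak, had 0 in the upper 50% of the list (percentile 37.0).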

Other observations

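The gene lists in the first paragraph and all tests in this part were chosen after the results were seen.

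The control hematopoietic library had peaks in several further groups of genes. Heat-shock proteins and co-chaperones had a peak in 16 of 79 genes in that library (3.30 in random lists, percentile 100) and in 9 in the S136/139A hematopoietic library (1.99, 100.0), with HSPA8 (score 17.6), DNAJB1 (13.1) and HSP90AA1 (10.6). Immediate early genes, which are induced within minutes by growth factors or stress, had a peak in 12 of 30 genes (1.06, percentile 100), led by PPP1R15A (101.7), CCN1 (80.4), DUSP1 (52.7) and FOS (44.8), and in 6 in the S136/139A hematopoietic library (0.48, 100.0), with CCN1 (11.3), KLF6 (10.6) and JUN (7.03). They were also frequent in undifferentiated (7, percentile 99.5) and neural (9, percentile 98.2) control cells, at 2.47 and 4.49 in random lists; with matching on the distance between genes the neural value was 96.9. Splicing factors of the SR and hnRNP families had a peak in 14 of 43 genes (1.46, percentile 100), with HNRNPA2B1 (91.4), SFPQ (41.9) and TRA2B (33.8), and in 5 in the S136/139A hematopoietic library (0.93, 99.9), against 0 in undifferentiated S139E cells (4.85, 0.33). Ribosomal protein genes had a peak in 12 of 80 genes in the control hematopoietic library (2.62, percentile 100) and in 0 in the S136/139A hematopoietic library (1.34, 13.1). In undifferentiated S139E cells 12 also had a peak (7.87, percentile 93.4), and 2 had one at a promoter (percentile 98.05 with promoter peaks only). With promoter peaks only, the heat-shock list had 2 genes in the control (percentile 96.5) and 1 in the S136/139A hematopoietic library (84.5), in the same order splicing factors 1 (89.3) and 2 (99.5), immediate early genes 2 (99.7) and 1 (97.7), and ribosomal proteins 5 in the control library (100.0). The lists were picked after the strongest peaks of all libraries had been seen, and 19 of the 34 wide regions of the control hematopoietic library held a peak of the S136/139A one, so the percentiles of neither are independent evidence.

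Repeats differed between the libraries. LTR elements held 11.4% of peaks (10.4 to 12.6) in undifferentiated and 9.51% (8.82 to 10.2) in neural control cells, 10.5% and 8.72% in S139E cells, but 1.59% (1.04 to 2.31) on the control hematopoietic day and 6.47% and 4.49% in S136/139A cells. LINE elements held 23.3% (19.4 to 27.6) of the undifferentiated S136/139A peaks and 8.11% to 15.6% of those of the other 6 libraries.

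One pattern was the group of 34 wide peaks in the control hematopoietic library. Carry-over of processed mRNA or cDNA as the whole cause is argued against by the 20.8% of bases under these peaks that lay outside annotated genes. Of the 34 peaks, 10 reached 1 kb or more past the gene. Another count, 16 centred in introns, does not bear on this, since the centre of a wide peak does not show where its reads lie. Deeper sequencing is argued against by the 3 libraries with more tags, which had at most 2 such peaks. The hematopoietic day or its handling fits: 19 of the 34 regions held a peak of the S136/139A hematopoietic library and 0 to 1 held a peak of each other library. No expression data were used, so it is not shown that these genes were induced on that day. Candidate explanations, not tested here, are H2A.X phosphorylation or unequal recovery of open chromatin over genes induced on that day. The induction could also come from the transfer of cells to suspension and harvest. An input library of the same day could help to separate phosphorylation from unequal recovery, but no day is given for the input libraries. The S136/139A hematopoietic library shares the day and the handling. Its introduced H2A.X cannot be phosphorylated at the replaced serines, so phosphorylation there would have to be of endogenous H2A.X.

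Another pattern was the distribution over chromosomes. In 4 libraries (undifferentiated and neural, control and S139E) chromosome 19 held 3.04 to 5.14 times as many peaks as chromosome 18, and in 3 libraries (the control hematopoietic and both S136/139A libraries) 0.857 to 1.03 times as many. A preference for gene-dense regions stays open: the 3 libraries with a low ratio (control hematopoietic, S136/139A undifferentiated and hematopoietic) had 79.8%, 59.8% and 68.4% of their peaks in gene spans, above, below and among the values of the 4 others (65.1% to 71.3%). A bias in base composition between libraries stays open too: in the same order the 3 libraries had 1.89%, 0% (0 of 433, which allows up to 0.693%) and 2.14% of peaks in CpG islands, among, below and among the values of the 4 others (1.64% to 3.32%), and no genome sequence was used here. The 3 libraries with a low ratio match no single mutation or day, but they are all the libraries of the hematopoietic day or of S136/139A cells. They were also the shortest lists, with 433 to 1640 peaks against 3469 to 8555 in the 4 others. Their shares in LTR elements were the lowest, at 1.59% to 6.47% against 8.72% to 11.4%. List length, cells and day cannot be told apart here, and no biological explanation was tested.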
